A study of Macaca fascicularis with 2 samples.

How the data were processed

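Single-cell RNA was measured in testis tissue of the cynomolgus monkey (Macaca fascicularis) with the 10x Genomics droplet method for 3' ends, version 3 chemistry. There were 2 libraries. One came from testis moved into the abdomen (UAT), a surgical model of cryptorchidism, and the other from contralateral testis left in the scrotum (CST). Each position had 1 library, and the number of animals was not given in the sources used here. Per the labels' protocols, minced tissue was kept at 37 °C with collagenase and dispase for no more than 30 min, strained at 40 µm and freed of red blood cells. The suspensions passed at over 80% viability and were loaded to recover 8000 to 10000 cells.

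The deposited matrices hold whole-number UMI counts per gene and barcode, not normalised, as the values and the file headers show. Per the matrix headers, the counts were made with Cell Ranger 5.0.0, whereas the submitters' processing notes name Cell Ranger 3.0.1. The same notes give the mouse build mm10, but the feature names are macaque RefSeq symbols, so the build behind the counts is open and no coordinates are given. Both libraries list the same 28845 features. Of these, 11526 carry only a LOC name with a gene number. A RefSeq gene table of the species held 5093 of those numbers, 721 features received a symbol from it, and 67 kept their LOC name because the symbol was already in use. Every barcode of the UAT library had at least 502 UMIs and every barcode of the CST library at least 500.

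Barcodes with at least 500 detected genes were kept, 12352 in UAT and 15001 in CST, with no limit on mitochondrial UMIs. Doublets were scored per library as the share of simulated doublets (2 per cell, sums of random pairs) among the neighbours of each cell on 30 principal components. The cells with the highest scores were removed at 0.8% per 1000 barcodes, which took 1221 cells (9.89%) from UAT and 1800 (12.0%) from CST. In a test on 4000 real cells of each library with 300 added sums of random pairs, 52.3% of the added pairs in UAT and 58.7% in CST were removed. Of the 4000 cells themselves, which can include real doublets, 6.9% in UAT and 9.3% in CST were removed. The remaining 11131 and 13201 cells were clustered together on 2000 variable genes, 40 components and 15 neighbours with the Leiden method at resolution 1, without batch integration. Libraries and positions are the same split here, so integration could have removed the contrast itself.

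Clusters were called X-like from 18 marker lists. A cluster stayed unnamed if fewer than 3 markers of the class were detected, if markers of another class outnumbered its own among its top 10 genes, if markers of different lineages scored alike, or if its median UMI count was under 1/3 of its library's with no marker among the top genes. These naming rules were set after the files were seen, the markers before. Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals. A share of 0 allows up to 3 cells of the total.

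UMI counts were summed per class and library and expressed as CPM of the class total. A class was compared if it had at least 50 cells in both libraries, which held for 7 classes. Ratios are UAT over CST with exact conditional binomial 95% intervals, and log2 ratios use a pseudocount of 10 CPM. All intervals cover counting error only, and say nothing of differences between animals or dissociations. With 1 library per group no test was possible, and no p-value or count of changed genes was made from cells.

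The samples, comparisons, markers, 28 gene lists and most alternatives were fixed before the data were examined. Genes named for a class had at least 100 CPM and 30 UMIs in the higher library. They also needed at least 25% of their level in the highest class of that library, and were the 10 highest and 10 lowest by the interval bound nearest no change. From each reported list, up to 4 members with the largest log2 ratio were added, as were class markers. Mitochondrial, ribosomal and haemoglobin genes and features without a symbol were left out. For each list with at least 3 members at 20 CPM in either library, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is no test. Members at least 1.5-fold higher or lower are counted by size.

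The interval and list steps were tested on simulated data with 200 genes changed by known folds. At the depth of the stromal-like class (7380 genes), 95.6% of intervals of unchanged genes held the true ratio, and no interval of a gene changed 2-fold missed the right side of 1. At the depth of the T or NK-like class (7055 genes) 96.3% held it, and 66.0% of genes changed 2-fold and 92.0% of genes changed 4-fold had an interval on the right side.

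Alternatives were a minimum of 200 or 1000 genes, no doublet removal, each library clustered alone, Leiden resolution 0.5 or 2, cells thinned to 1000 UMIs, scaling by the median gene ratio, the mean of per-cell CPM, pseudocounts of 1 and 50 CPM, and list members at 5 or 100 CPM. A free RNA profile, taken as each library's summed counts, was also removed from class sums at a share estimated from markers that the class should lack. Added after seeing the data were a limit of 20% mitochondrial UMIs, only clusters with at least 50 cells of both libraries, and the use of the other alternatives on further results. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.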

Results

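Transcriptomes of single cells were compared between cynomolgus monkey testis placed in the abdomen (UAT) and contralateral testis in the scrotum (CST). The design asks how artificial unilateral cryptorchidism affects spermatogenesis and the cells around it. The UAT library held 12564 barcodes and 111047299 UMIs, with a median of 7194 UMIs per barcode. The CST library held 15952 barcodes and 197225937 UMIs, with a median of 5439. There was 1 library per position, so the differences below are between these libraries and have no replicate check. The 5 most abundant features of the CST library were the spermatid genes PRM1, PRM2, TNP1, TNP2 and HMGB4, and PRM1, a protamine that packs sperm DNA, took 4.15% of its UMIs. In the UAT library, PRM1 took 3.51e-05% of UMIs, and mitochondrial transcripts and the stromal gene DCN were among the 10 most abundant.

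The library of the abdominal testis held almost no meiotic or postmeiotic germ cells, and nearly all of its germ cells were spermatogonia. Germ cells made up 293 of 11131 UAT cells (2.63%, 95% interval 2.34 to 2.95) and 9391 of 13201 CST cells (71.1%, 70.4 to 71.9). Spermatid-like cells, the haploid cells that mature into sperm, were 1 of 293 germ cells in UAT (0.341%, 0.00864 to 1.89) and 5878 of 9391 in CST (62.6%, 61.6 to 63.6). Spermatocyte-like cells, the cells in meiosis, were 3 of 293 in UAT (1.02%, 0.212 to 2.96) and 2622 of 9391 in CST (27.9%, 27.0 to 28.8). Spermatogonia-like cells were 289 of 293 in UAT (98.6%) and 891 of 9391 in CST (9.49%).

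By stage, the CST germ cells comprised 211 early and 2411 late spermatocyte-like cells, 2761 round and 3117 elongating spermatid-like cells. The UAT library had 2 early and 1 late spermatocyte-like cells, 1 round and 0 elongating spermatid-like cells, the last of which allows a share of up to 1.02%. The single UAT round spermatid-like barcode had 684 UMIs and the late spermatocyte-like one 1229, and neither had a UMI of PRM1. Cells without a class were 0.602% of UAT and 7.84% of CST cells. Most of these CST cells lay in a cluster of 917 cells with a median of 1037 UMIs and 11.8% mitochondrial UMIs. Shares of all cells depend on how each tissue dissociated, and the share of germ cells moves with the somatic yield. Per 100 endothelial-like cells, there were 19.4 spermatogonia-like cells in UAT and 257.5 in CST.

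**Figure D1:**
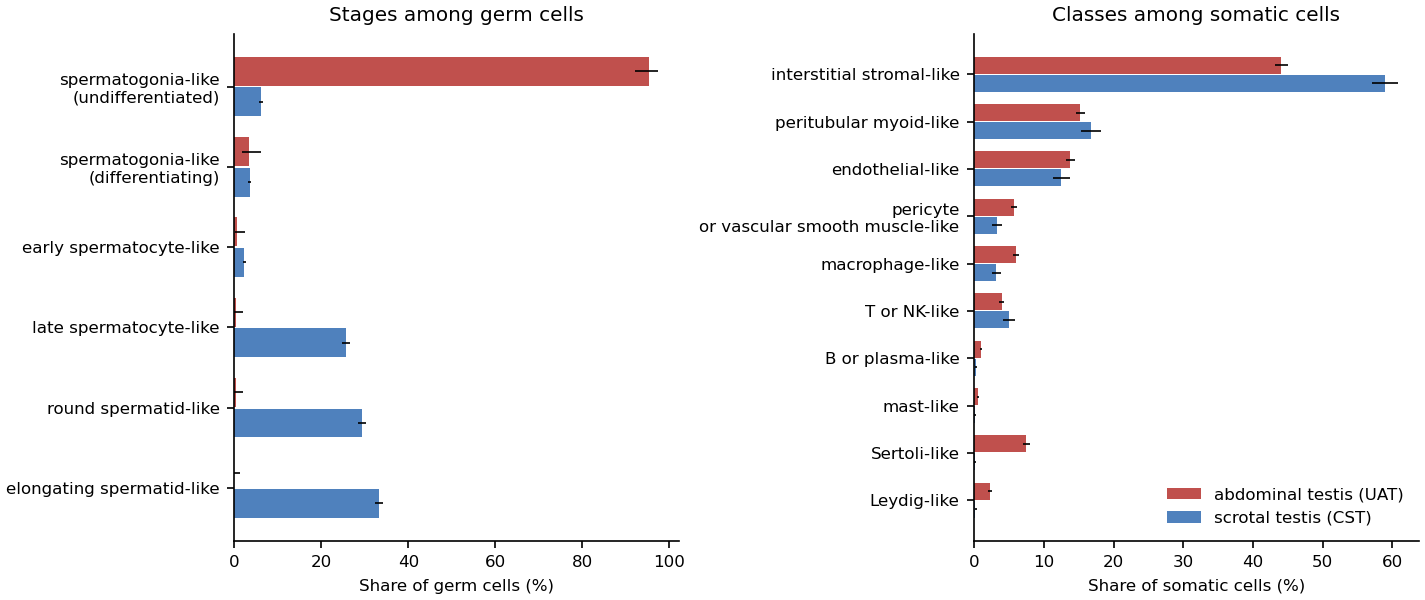
Shares (percent, horizontal axis) of germ cell stages among germ cells (left) and of somatic classes among somatic cells (right) in the abdominal (UAT, red) and scrotal (CST, blue) testis, 1 library each, with exact 95% binomial intervals as black lines. Spermatid-like cells made up 62.6% of CST germ cells and 0.341% of UAT germ cells, while Sertoli-like and Leydig-like cells were 7.44% and 2.29% of UAT somatic cells and 0.108% and 0.180% of CST somatic cells.

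In UMIs summed over spermatogonia-like cells, 8 of 12 markers of the differentiating state were lower in UAT by their counting interval and 3 higher. Of 18 markers of the undifferentiated state, 9 were higher and 3 lower. Over all spermatogonia-like cells, PIWIL4, a marker of the most primitive human spermatogonia, stood at 159 CPM in UAT and 65.2 in CST, a ratio of 2.44 (2.18 to 2.73). NANOS2, which keeps spermatogonia undifferentiated, had a ratio of 2.63 (1.95 to 3.56) and ZBTB16 of 2.33 (1.92 to 2.83). KIT, the receptor that marks differentiating spermatogonia, stood at 22.4 CPM in UAT and 97.3 in CST (ratio 0.230, 0.185 to 0.284). STRA8, which starts meiosis, had a ratio of 0.174 (0.0931 to 0.301) and DMRTB1 of 0.181 (0.161 to 0.203). The proliferation genes MKI67 (148 and 417 CPM) and TOP2A (261 and 879 CPM) were also lower. Lower among the undifferentiated markers were FGFR3 (0.646, 0.528 to 0.785), PHGDH (0.644, 0.472 to 0.869) and SOHLH1 (0.754, 0.694 to 0.818). Higher among the differentiating ones were UCHL1, NANOS3, which is on both lists, and ELAVL2 (1.38, 1.31 to 1.45). EGR4, MSANTD3, TSPAN33, GFRA1, DUSP6 and MAGEA4 had intervals that held 1. Spermatid RNA was present in the CST cells, with PRM1 at 1295 CPM against 0.231 in UAT. With the free RNA profile taken out (7.11% in UAT, 5.61% in CST), the 8 lower and the 9 higher markers stayed on their sides. Cells of the differentiating cluster were 10 of 289 spermatogonia-like cells in UAT (3.46%, 1.67 to 6.27) and 327 of 891 in CST (36.7%, 33.5 to 40.0). This share rested on the clustering, and with each library clustered alone it was 82.3% in UAT and 71.4% in CST. The summed counts weigh deep cells more. In CST, 4546173 UMIs came from the 327 cells of the differentiating cluster and 3967583 from the 564 undifferentiated cells. In UAT these were 170301 and 4162164 UMIs. The marker ratios thus partly follow the weight of that cluster, which was named from the same markers. They need not show a shift per cell, and levels averaged per cell were not computed for the pool.

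Somatic cells numbered 10771 in UAT and 2775 in CST, and the classes that support germ cells and make androgen had larger shares in UAT. Sertoli-like cells, the nurse cells of the tubules, were 801 (7.44% of somatic cells, 6.95 to 7.95) in UAT and 3 (0.108%, 0.0223 to 0.316) in CST. Leydig-like cells were 247 (2.29%, 2.02 to 2.59) and 5 (0.180%, 0.0585 to 0.420). The UAT Sertoli-like cells had 7035 UMIs of AMH (643 CPM), 13432 of INHA (1228 CPM) and 494 of FSHR (45.1 CPM), which encode anti-Müllerian hormone, the inhibin alpha chain and the receptor for follicle-stimulating hormone. The UAT Leydig-like cells had 44055 CPM of INSL3, 5411 CPM of CYP17A1 and 716 CPM of STAR, of which the last 2 serve steroid synthesis. The CST classes were too small for a comparison of levels. The CST shares depended on the processing. Sertoli-like cells were 0.501% of CST somatic cells with a minimum of 200 genes, 1.29% with 1000 genes and 0% with each library clustered alone. Without doublet removal, the CST library had 80 Sertoli-like cells (2.57%) and 24 Leydig-like cells (0.771%), and PRM1 in these Sertoli-like cells was at 10013 CPM against 0.222 CPM in UAT. Rete or epididymal epithelial-like and erythroid-like clusters were found in neither library.

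Among the other somatic classes, stromal-like cells were 44.1% of somatic cells in UAT (43.1 to 45.03) and 58.9% in CST (57.1 to 60.8). Macrophage-like cells were 5.97% (5.53 to 6.43) and 3.10% (2.49 to 3.81), and pericyte or vascular smooth muscle-like cells 5.70% (5.27 to 6.16) and 3.21% (2.58 to 3.93). Peritubular myoid-like cells were 15.3% and 16.7%, endothelial-like cells 13.8% and 12.5%, and T or NK-like cells 3.96% and 4.97%. B or plasma-like cells numbered 105 and 6, and mast-like cells 58 and 3.

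RBM3, an RNA-binding protein induced by mild cold, was lower in UAT in all 7 classes compared. It stood at 143 CPM in UAT and 479 in CST in undifferentiated spermatogonia-like cells, a ratio of 0.298 (0.271 to 0.327). The ratio was 0.220 (0.202 to 0.241) in peritubular myoid-like, 0.285 (0.273 to 0.298) in stromal-like and 0.371 (0.336 to 0.412) in endothelial-like cells. In pericyte or vascular smooth muscle-like cells it was 0.422 (0.340 to 0.529), in T or NK-like cells 0.510 (0.417 to 0.627) and in macrophage-like cells 0.569 (0.494 to 0.659). CIRBP, another cold-inducible RNA-binding protein, was also lower in all 7, from 0.479 (0.444 to 0.517) in the spermatogonia-like cells to 0.670 (0.553 to 0.819) in macrophage-like cells. The list's remaining member, SRSF5, was lower in spermatogonia-like cells (0.600, 0.544 to 0.661) and higher in T or NK-like cells (1.68, 1.38 to 2.07).

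Heat-shock proteins and co-chaperones, which fold proteins and are in part induced by heat, had list medians above 0 in 6 of the 7 classes. In undifferentiated spermatogonia-like cells, 11 of 19 measured members were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.79, above that of every matched random list. Which cells made up this class depended on the clustering. FKBP4 had a ratio of 2.39 (2.10 to 2.71), HSPB1 of 2.21 (2.05 to 2.39) and AHSA1 of 2.23 (1.98 to 2.53). HSP90AB1, the constitutive cytosolic HSP90, stood at 4301 CPM in UAT and 2080 in CST (2.07, 2.01 to 2.12). The median log2 ratio of the list was 0.44 in endothelial-like and in macrophage-like cells, 0.35 in myoid-like cells and 0.34 in stromal-like and in pericyte-like cells, at percentile 99.7 of random lists or above. Members at least 1.5-fold higher were 7 of 20, 6 of 18, 6 of 21, 6 of 20 and 9 of 21 in these classes, and 0, 1, 0, 0 and 3 were lower. For list medians, the alternatives left out gene minimums, other Leiden resolutions, separate clustering and thinning. Over the alternatives tried, the medians ran from 0.35 to 0.58, 0.22 to 0.60, 0.23 to 0.44, 0.20 to 0.62 and 0.11 to 0.88 in the same order, and from 0.58 to 0.86 in spermatogonia-like cells. In T or NK-like cells it was -0.05 at percentile 33.7, with 3 of 21 members higher and 5 lower, and it ran from -0.15 to 0.16. HSP90AB1 itself was higher in all 7 classes, by 1.83 (1.60 to 2.10) to 2.54 (2.12 to 3.06). The inducible HSPA1A and HSPA1B could not be matched to a feature name.

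**Figure D2:**
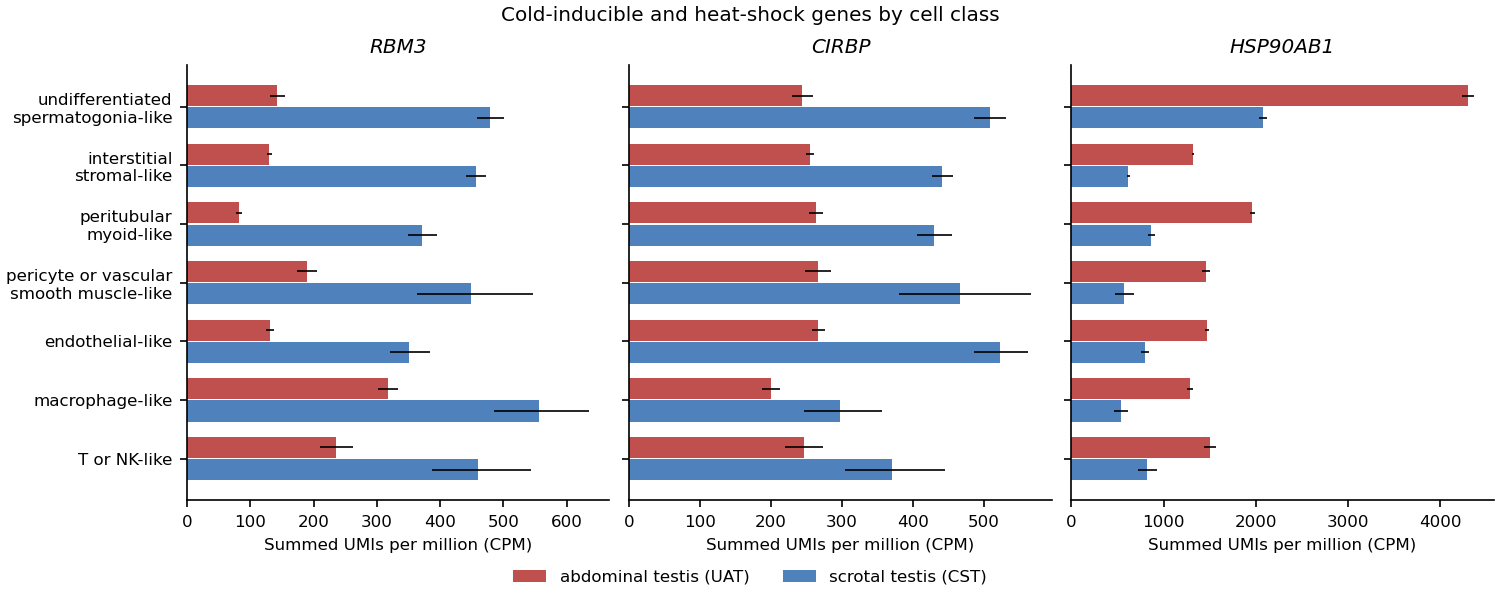
Levels of RBM3, CIRBP and HSP90AB1 (CPM of summed UMIs, horizontal axes) in the 7 cell classes compared, in the abdominal (UAT, red) and scrotal (CST, blue) testis, 1 library each, with exact Poisson 95% intervals as black lines. CIRBP lay between 199 and 267 CPM in UAT and between 298 and 523 CPM in CST, and HSP90AB1 was higher in UAT in each of the 7 classes.

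In undifferentiated spermatogonia-like cells (279 in UAT, 564 in CST), the other named genes higher in UAT included the histone genes H2BC1 (2.19, 2.05 to 2.35) and H1-3 (2.10, 1.96 to 2.26), the malic enzyme gene ME2 (2.13, 1.89 to 2.41) and the co-chaperone gene STIP1 (2.01, 1.83 to 2.21). Lower in UAT, after RBM3, were SNRPB, a core splicing protein (0.402, 0.373 to 0.432), CD9, a tetraspanin (0.386, 0.323 to 0.459), DLK1 (0.414, 0.369 to 0.464) and BSG (0.453, 0.423 to 0.486). Nuclear-encoded oxidative phosphorylation genes had a median log2 ratio of -0.07, with 1 of 23 members lower and 0 higher, and the median ran from -0.10 to 0.011 over the alternatives. The G2M cell cycle list had a median of -0.26 at percentile 0.0400, with 4 of 22 members lower. It ran from -0.52 to -0.14 over the alternatives, free RNA taken out among them. CCNA1, AURKA, AURKC and NEK2 of this list are also late spermatocyte markers. In the somatic classes its medians lay between -1.53 (macrophage-like) and -2.44 (pericyte-like), so free RNA of CST germ cells could lower it here too. Apoptosis genes had a median of -0.03 (-0.16 to 0.032 over the alternatives), and 0 of 15 members passed 1.5-fold either way. Median depth in this class was 8222 UMIs in UAT and 2864 in CST. Membership of the class rested on the clustering. With each library clustered alone, 82.3% of UAT and 71.4% of CST spermatogonia-like cells were called differentiating. The ratios of this class, those of RBM3 and heat-shock genes included, may therefore compare different mixes of states.

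Stromal-like cells had lower levels of several matrix genes in UAT. COL1A1, the main fibrillar collagen chain, was at 995 CPM in UAT and 2985 in CST, a ratio of 0.333 (0.328 to 0.339), and COL1A2 had a ratio of 0.445 (0.439 to 0.452). IGFBP5 (0.256, 0.248 to 0.265), PI16 (0.315, 0.306 to 0.324), MFAP5 (0.316, 0.304 to 0.328) and CLEC3B (0.347, 0.342 to 0.353) were lower too. Of the extracellular matrix list, 10 of 32 members were lower and 2 higher (median log2 -0.29, percentile 0.0200, -0.39 to -0.20 over the alternatives), COL6A3 among the latter (2.07, 1.99 to 2.15). Higher in UAT were the apolipoprotein gene APOD (3.61, 3.50 to 3.73), the complement genes C4B (3.66, 3.25 to 4.14) and C7 (2.60, 2.47 to 2.74), and GPX3 (3.13, 2.82 to 3.47), a secreted antioxidant enzyme. CDKN1A, a cell cycle inhibitor from the apoptosis list, was at 81.8 and 29.3 CPM (2.79, 2.43 to 3.23). The libraries filled different stromal-like clusters, since 4316 UAT and 229 CST cells lay in one and 9 UAT and 1370 CST cells in another, led by CLEC3B, PI16, COL1A1 and MFAP5. Within the shared cluster, the log2 ratio was -0.33 for CLEC3B (class -1.52), -0.73 for PI16 (-1.64), -0.83 for MFAP5 (-1.61), -1.33 for IGFBP5 (-1.91) and 0.47 for C7 (1.34). It was -1.76 for COL1A1 (-1.58), 1.55 for APOD (1.83), 1.48 for C4B (1.64) and 1.60 for GPX3 (1.48).

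The same direction was seen in peritubular myoid-like cells, the contractile cells around the tubules, where 18 of 30 matrix genes were lower in UAT and 0 higher (median log2 -0.69, percentile 0.00, -0.81 to -0.53 over the alternatives). CTGF, a matrix-associated growth factor, had a ratio of 0.157 (0.145 to 0.170), COL3A1 of 0.219 (0.210 to 0.230), COL1A2 of 0.224 (0.214 to 0.235) and THY1 of 0.187 (0.164 to 0.213). APOD was higher here as well (4.79, 4.41 to 5.20), as were ABCA8 (3.48, 3.16 to 3.85), IFITM1 (2.75, 2.52 to 3.01) and CDKN1A (3.87, 2.89 to 5.29). Here too the clusters differed, with 1641 UAT and 78 CST cells in one and 2 UAT and 386 CST cells in the other. CD93 had a class ratio of 0.206 (0.182 to 0.232), but was higher in UAT within the cluster that both libraries shared.

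Endothelial-like cells (1486 and 346) had lower interferon-response genes in UAT, with 8 of 18 members lower and 0 higher (median log2 -0.56, percentile 0.00, -0.63 to -0.43 over the alternatives). ISG15 had a ratio of 0.243 (0.209 to 0.283), IFI6 of 0.374 (0.354 to 0.395), MX2 of 0.180 (0.139 to 0.235) and OAS1 of 0.371 (0.310 to 0.447). Stromal-like cells also had a lower interferon list (median log2 -0.48), with 6 of 13 members lower and 2 higher. Its median was -0.30 in pericyte-like, 0.08 in myoid-like, 0.15 in spermatogonia-like and 0.18 in T or NK-like cells. CXCL12, a chemokine, was at 326 CPM in UAT and 1484 in CST (0.220, 0.208 to 0.232), and PLAT, the tissue plasminogen activator, had a ratio of 0.283 (0.241 to 0.332). Higher in UAT were IL1R1 (4.12, 3.32 to 5.18), TFPI (3.73, 3.01 to 4.68) and LEPR (2.58, 2.23 to 3.004). The lymphatic genes MMRN1, PROX1, ANGPT2 and LYVE1 also ranked among the higher genes, through a cluster of 104 UAT and 0 CST cells that they define. Without doublet removal, MMRN1, PROX1 and ANGPT2 were lower in UAT.

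Macrophage-like cells (643 and 86) showed more unfolded protein response transcripts in UAT, the genes that raise the folding capacity of the endoplasmic reticulum. Of 15 members, 10 were higher and 0 lower (median log2 1.08, above every random list, 0.85 to 1.27 over the alternatives). The chaperone gene HSPA5 was at 1108 and 277 CPM (4.00, 3.31 to 4.88), and PDIA4 (4.24, 2.97 to 6.26), SDF2L1 (3.88, 2.497 to 6.38) and HSP90B1 (3.13, 2.72 to 3.63) went the same way. Of the interferon-response genes, 7 of 16 members were lower and 1 higher (median log2 -0.53, percentile 0.00, -1.26 to -0.27 over the alternatives). IFI6 had a ratio of 0.287 (0.253 to 0.327), but 1 of the 86 CST cells held 31.3% of its UMIs there and 5 cells held 50.3%. The top 5 CST cells of each gene, not always the same cells, held 51.0% for MX1 and 52.0% for MX2. The calprotectin genes S100A9 (14.3, 9.97 to 21.4) and S100A8 (5.75, 4.68 to 7.14) were higher, and 63 UAT and 6 CST cells formed a cluster led by them. Of their UMIs in the 643 UAT cells, 5 cells held 43.8% for S100A9 and 37.9% for S100A8. Among the named genes of this class, CCL17 (0.0189, 0.0142 to 0.0248) and SPP1 (29.5, 14.3 to 73.4) had the most extreme ratios. Each came from few cells, 97.9% of CCL17 UMIs in CST and 77.5% of SPP1 UMIs in UAT from 5 cells.

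Few cells were compared in the remaining classes. In T or NK-like cells (426 and 138), ZEB2 (5.58, 2.98 to 11.8), KLRB1 (3.86, 2.62 to 5.92) and BCL11B (2.24, 1.70 to 3.004) were higher in UAT, and TIGIT, an inhibitory receptor, was lower (0.378, 0.301 to 0.478). The lower values of CGA, CCL20, IRF8, TNFRSF18 and CTLA4 in this class rested on few CST cells, since 5 cells held at least 80.7% of their UMIs. In pericyte or vascular smooth muscle-like cells (614 and 89), ID4 (6.29, 4.37 to 9.41), CYR61 (3.08, 2.52 to 3.79) and HSPB1 (3.09, 2.48 to 3.90) were higher and SLC12A2 (0.209, 0.165 to 0.266) and NDUFA4L2 (0.260, 0.217 to 0.314) lower. INSL3, ranked lowest among the named genes of that class by interval bound (ratio 0.0600, 0.0502 to 0.0716), came from 1 cell, with 278 of 279 CST UMIs. Scaling by the median gene ratio shifted log2 values by 0.11 in T or NK-like cells and by less in the other classes.

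The 9 matched mitochondrial-encoded genes had list medians between 0.41 and 0.83 over the 7 classes, and 0.17 was the lowest value of an alternative, in T or NK-like cells. Members at least 1.5-fold higher in UAT were 5 of 9 in stromal-like, myoid-like and spermatogonia-like cells, 3 in endothelial-like and pericyte-like cells and 2 in macrophage-like and T or NK-like cells, and 0 were lower. Immediate early genes, which dissociation can induce, had medians of 0.65 in endothelial-like, 0.63 in pericyte-like, 0.50 in T or NK-like, 0.39 in myoid-like, 0.27 in macrophage-like and 0.07 in stromal-like cells. Over the alternatives these stayed above 0 except in stromal-like cells (-0.0084 to 0.19). As the mean share of all UMIs per cell, the same genes were higher in UAT in each of the 7 classes, in stromal-like cells by a log2 of 0.40 (235 and 178 per 10000 UMIs) and in myoid-like cells by 0.61. In undifferentiated spermatogonia-like cells their median was 0.71, and it was -1.45 once the free RNA profile was taken out. The matrix list had medians of 0.67 there and 0.69 in T or NK-like cells, which became -0.22 and -1.45. This removal can take more of a stromal gene than a class held. DCN made up 0.680% of UAT UMIs but stood at 366 CPM in UAT T or NK-like cells, where the share removed was 10.5%. Levels below 0 were set to 0, so the negative matrix medians decide nothing about these classes. The same limit holds for the -1.45 of immediate early genes in spermatogonia-like cells. Those genes were 18.8 per 10000 UMIs there in UAT, but 160 to 371 in the UAT somatic classes compared. With 7.40% of the profile removed, much of their level in UAT spermatogonia-like cells can be lost, so the -1.45 decides nothing either. Sperm genes appeared in CST somatic classes, where PRM1 lay between 1571 and 6537 CPM, against at most 1.46 CPM in the same UAT classes. Lower germ cell transcripts in UAT somatic classes are therefore not reported as differences of those classes, nor are the lower acrosome, flagellum and sperm chromatin lists of undifferentiated spermatogonia-like cells (medians -1.36, -1.19 and -1.99), whose CST cells had 1598 CPM of PRM1.

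**Figure D3:**
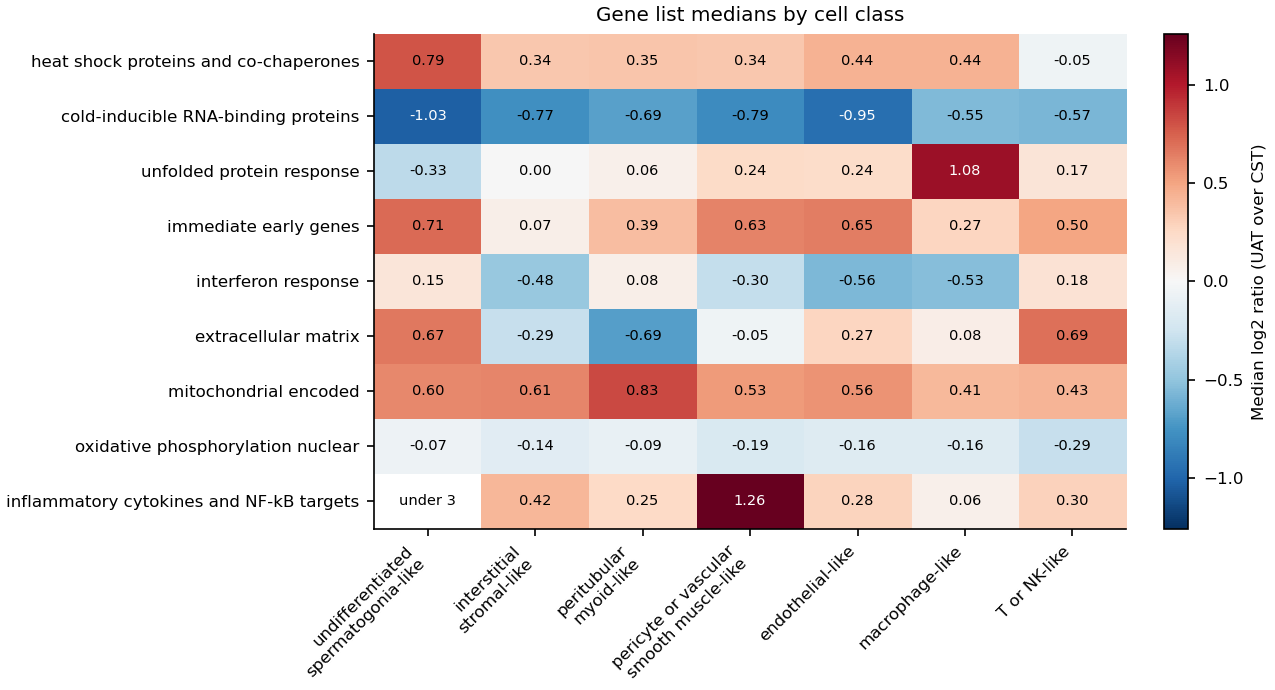
Median log2 ratio (UAT over CST, colour scale and printed values) of 9 gene lists fixed in advance, in the 7 cell classes compared, 1 library per position; a list with under 3 measured members has no value. Heat-shock medians lie between 0.34 and 0.79 in 6 classes and at -0.05 in T or NK-like cells, and the matrix medians of spermatogonia-like (0.67), T or NK-like (0.69) and endothelial-like (0.27) cells turn negative with free RNA taken out. That step can remove more matrix RNA than a class held.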

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

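The tests of RBM3 alone, of the expected number of spermatids and of further library differences were chosen after the results were seen. So were the omission of T or NK-like and spermatogonia-like cells from the matched-cell count and the demand that its counting range clear the bound.

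The unfolded protein response list differed between classes. Its median log2 ratio was 1.08 in macrophage-like cells and -0.33 in undifferentiated spermatogonia-like cells, where 0 of 15 members were higher and 2 lower. The difference between the classes was not tested, since there was 1 library per position. A cluster of 67 UAT cells (0.602% of that library) and 13 CST cells was left out of the comparisons, because genes of endothelial cells and of pericytes lay together among its top genes.

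RBM3 was lower in UAT in 7 classes and the heat-shock median was higher in 6, T or NK-like cells being the exception. For RBM3, free RNA from CST germ cells was argued against, since RBM3 in the free profile was lower in CST (69.3 CPM) than in UAT (130.5 CPM). With that profile taken out, 7 of 7 classes kept an RBM3 log2 ratio below -0.5 (-0.85 to -2.20). Each ratio moved further below 0, as removal of a CST profile poor in RBM3 would do, so this count adds little. The heat-shock rise was not part of that test. A dissociation response that differs between the libraries stays open for the pair of results: among cells matched on immediate early genes, 4 of 5 classes kept 75% or more of both values (counting range 1 to 5), or 5 of 6 with spermatogonia-like cells and 6 of 7 with T or NK-like cells too. T or NK-like cells had no heat-shock rise to keep (median -0.05, share kept -432% to 416% by counting), so that class decides nothing for the pair. Matching lowered the log2 difference in immediate early genes from between 0.33 and 0.66 to between 0.05 and 0.09 in 6 classes, but left 0.70 of 1.33 in spermatogonia-like cells, where 1 band held most cells, so that class decides nothing. For RBM3 alone, such a response as tracked by immediate early genes was argued against as the whole cause in 4 of 6 classes. These were endothelial-like, stromal-like, myoid-like and T or NK-like cells, where the lower bound of the ratio kept was at least 75%. That response stays open in the others. A handling difference that moves RBM3 without these genes was not tested and stays open in all classes. Testis position, which the design names, cannot be told apart from another difference between the 2 libraries, with 1 library per position.

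Spermatid-like cells were all but absent from UAT. Had spermatids been present in the tissue and lysed when cells were isolated, their RNA would be looked for in the suspension, but the highest PRM1 level of a UAT somatic class was 0.0274% of that in the same CST class; a loss of intact spermatids was not tested and stays open. Fewer cells or reads in the UAT library were argued against as well, since 183 spermatids were expected among the UAT germ cells at the CST share and 1 was seen. Testis position stays open as an untested explanation, with 1 library per position. The loss of spermatocytes was not tested apart from that of spermatids.

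Stromal-like cells of the libraries lay in different clusters. Without genes higher in germ cells (6024 genes left), the median share of cross-library neighbours of CST stromal-like cells was 0% of a random mix, but it was 0% with all genes too and so decides nothing. The mean was 16.2%, against 0.943% with all genes, and lay between the bounds set for the median (the mean was computed first), so free RNA from germ cells of the CST library stays open. Different stromal subtypes taken into the 2 libraries stay open too, since the named genes kept a median of 69.9% of their log2 ratio within the shared cluster.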

How the results depend on the processing

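Added after seeing the data were the limit of 20% mitochondrial UMIs, the restriction to shared clusters, free RNA removal for list medians and spermatogonia markers, Leiden resolutions for spermatogonia and somatic shares, and thinning for shares other than that of spermatids. The counts of classes were recomputed with pseudocounts of 1 and 50 CPM, median ratio scaling, the mean of per-cell CPM, free RNA taken out, no doublet removal, the mitochondrial limit and shared clusters. RBM3 was lower in UAT in 7 of 7 classes under each of these. The heat-shock median was above 0 in 6 classes, or in 7 with free RNA taken out, without doublet removal and with members at 100 CPM, and in 6 with members at 5 CPM. No count of classes, gene level or list median was recomputed under the other clusterings, gene minimums or thinning. Values for 171 genes (31 of them in pooled spermatogonia, only with free RNA taken out) stayed within their interval in 807 comparisons, moved beyond it in 339 and reversed in 5. For 55 list medians these numbers were 431, 105 and 9. Of comparisons of 26 shares, 138 stayed within the interval and 70 moved. For the values below, the cause was not tested.

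With a minimum of 1000 genes, germ cells were 2.004% of UAT and 69.4% of CST cells, UAT spermatids 0% of germ cells, and differentiating cells 49.5% of CST spermatogonia. Among somatic cells, Sertoli-like cells were 5.87% in UAT and 1.29% in CST, and stromal-like cells 45.4% in UAT. With a minimum of 200 genes, germ cells were 65.9% of CST cells, spermatids 0% of UAT and 58.5% of CST germ cells, Sertoli-like cells 8.01% and 0.501%, and stromal-like cells 45.04% and 60.9% (UAT and CST).

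Without doublet removal, germ cells were 66.6% of CST cells and spermatids 0% of UAT and 68.5% of CST germ cells. Of CST somatic cells, 2.57% were Sertoli-like and 0.771% Leydig-like, and stromal-like cells were 40.4% in UAT and 52.8% in CST. The endothelial log2 ratios of MMRN1 (-0.48), PROX1 (-0.36) and ANGPT2 (-0.60) were reversed.

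With the libraries clustered alone, germ cells were 65.1% of CST cells, UAT spermatids 0%, and differentiating cells 82.3% of UAT and 71.4% of CST spermatogonia, which reversed the order of the libraries. In CST, Sertoli-like and Leydig-like cells were 0% and stromal-like cells 60.9%. At Leiden resolution 0.5, germ cells were 68.4% of CST cells. At resolution 2 they were 66.6%, UAT spermatids 0%, differentiating cells 36.3% of UAT and 69.8% of CST spermatogonia, and stromal-like cells 42.9% and 63.7%.

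Thinned to 1000 UMIs, germ cells were 73.0% of CST cells, spermatids 0% of UAT and 63.8% of CST germ cells, differentiating cells 8.30% and 55.3% of spermatogonia, and UAT Sertoli-like cells 6.53%. With at most 20% mitochondrial UMIs, germ cells were 72.9% of CST cells and spermatids 61.4% of CST germ cells. Sertoli-like cells were 5.99% and Leydig-like cells 2.01% in UAT, stromal-like cells 45.6% and 61.1%, and the inflammatory list of pericyte-like cells had a median of -0.046.

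With free RNA taken out, median log2 ratios reversed for immediate early genes in stromal-like (-0.0084) and undifferentiated spermatogonia-like cells (-1.45). They also reversed for extracellular matrix in T or NK-like (-1.45), endothelial-like (-0.30) and spermatogonia-like cells (-0.22), and for interferon response in spermatogonia-like cells (-0.12). Since this step can remove more of a gene from other classes than a class held, the matrix reversals decide nothing. The same holds for immediate early genes in spermatogonia-like cells. The unfolded protein response in T or NK-like cells was -0.016 with members at 100 CPM. Within clusters shared by both libraries, the inflammatory list of stromal-like cells was -0.17, INSL3 in pericyte-like cells 2.62 and CD93 in myoid-like cells 0.95.

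No paired analysis was possible because there was 1 library per position and the labels number no animals. Depth limits the small classes most. In simulated counts without variation between cells, at the depth of the T or NK-like class, 66.0% of genes changed 2-fold had an interval on the right side of 1. Shares of 0 among 293 UAT germ cells allow up to 1.02%.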

Other observations

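The CST library has 15952 barcodes, more than the 15000 cells that the loading volume and concentration in the labels give. In CST, several germ classes fell into clusters of low and high depth, such as late spermatocyte-like clusters with medians of 2177 and 44158 UMIs and elongating spermatid-like clusters with medians of 1254.5 and 18722.5. Mitochondrial transcripts were 7.80% of UMIs in UAT and 2.08% in CST. These whole-library values depend on the mix of cells, since elongating spermatid-like clusters, with 0 UAT cells, had medians from 0.040% to 0.59%. Without doublet removal, where both libraries had at least 50 Sertoli-like cells, the cold-inducible list had a median log2 ratio of -0.96 in that class and the heat-shock list of -0.05, at percentile 56.2 of random lists. The CST cells of that class carried 10013 CPM of PRM1, so these values describe cells mixed with spermatid RNA.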
